A study of Mus musculus with 3 samples.

How the data were processed

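CD8 T cells of 3 cultures were profiled with the 10x Genomics 3′ kit, version 2, per the labels, with 1 library per condition and a target of 10000 cells each. Naive cells from OT-I spleens were activated with 10 ug/ml plate-bound anti-CD3, 0.5 ug/ml anti-CD28 and 10 ng/ml IL-2. The effector culture then had 10 ng/ml IL-2 and the memory culture 50 ng/ml IL-15. Before loading, the activated culture had a dead-cell removal step, which the others did not, and viability was about 90% for activated, 90% for effector and 70% for memory cells, per the labels. The groups differ in these points as well as in treatment, and activated cells differ from the others in time.

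The deposited matrices hold counts, raw UMIs per gene and barcode, with no normalization by the authors. The authors used Cell Ranger, whose version is not given in the sources used here, and Seurat 2.3.4, with the mm10 build GRCm38.p4, per the submitters' processing notes. Which tool made which file is not given there. The deposited cell table gives counts of UMIs and genes per cell and the percent of UMIs from mitochondrially encoded protein genes. It also gives fine clusters, states and the reasons for leaving clusters out, all by the authors. The merged matrix held 22254 cells and 18204 genes, and each cell's total equalled the deposited UMI count in 22254 of 22254 cells. The unfiltered matrices list 737280 barcodes and 27998 genes. Clusters named by the authors as high in Actb, low in genes, apoptotic or exhausted were left out here as there: 875 of 6734 activated cells (13.0%), 44 of 8344 effector cells (0.527%) and 510 of 7176 memory cells (7.11%).

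UMIs were summed over the remaining cells of each library and divided by the library's sum to give CPM. No test was made, since cells are not replicates. A printed fold is the plain ratio of CPM, and its 95% interval is the exact conditional binomial (Clopper-Pearson) one. Log2 folds are of CPM with a pseudocount of 1, which understates the change of low genes. A gene counted as different at 2-fold on that scale with at least 10 CPM in the higher library. For a gene with 0 counts the fold is a lower bound against a floor of 3 counts in that library. Shares have exact binomial (Clopper-Pearson) and summed levels exact Poisson intervals, all for counting error only. For a list, the median over members of at least 10 CPM in either library is given. Its percentile among 10000 random lists of the same size, drawn within 20 bins of expression, is printed for some lists. Both describe these libraries only. Shares of cells with a UMI were taken after thinning each cell to 1600 UMIs, which left out 421 activated cells. That number is the lowest 10th percentile of depth among the libraries, 1690 UMIs in activated cells, rounded down to a multiple of 100. Cell states compared with each other came from the same library. Some single-gene values, and a weighed comparison of memory states that rests on them, are not reported here.

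The 36 gene lists with 684 genes, the 12 check genes, the rule for naming genes, the main settings and most alternatives were fixed before the data were examined. Named genes are the check genes, the 10 genes with the highest fold per comparison and direction at 100 CPM or more whose interval lies above 2 (leaving out mitochondrial, ribosomal protein, unnamed model and receptor variable genes), and up to 4 members per list by size of fold; the text gives a part of them. Genes given by state, H2-Aa, Cd74 and the photoreceptor and haemoglobin genes were chosen after their values were seen or for checks. Some members of the B cell, myeloid, gamma-delta T cell and CD8 T cell lists were not matched and not used here. Positions are from GENCODE M21 on GRCm38, matched by gene identifier for 255 of 255 named genes, 254 with the same name; these are whole-gene spans of protein-coding genes.

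Alternatives were TMM factors, median-of-ratios size factors, totals without ribosomal protein and mitochondrial genes, the mean of each cell's own CPM, pseudocounts of 0.1 and 5 CPM, no minimum and a minimum of 50 CPM, a filter of at least 1000 UMIs and under 10% mitochondrial UMIs, leaving out the 5% of cells with the most UMIs, cells with no UMI of Mki67, Top2a, Cdk1 or Birc5, thinned cells and subtraction of 5% free RNA. Added after the data were seen were all deposited cells, leaving out Naive cells, and the state comparisons. Doublets were sought with Scrublet at an expected rate of 8%, and it called 0 of 5859, 0 of 8300 and 0 of 6666 cells. The caller thus did not work here and gave no alternative. Leaving out the deepest 5% also takes out deep single cells and can keep doublets of shallow cells, so it does not replace doublet removal. Barcodes of 1 to 50 UMIs were read beside the cells. For genes abundant in another library they also hold molecules on barcodes that are cells there, 86.9% of the UMIs of 5 effector genes in the activated library. Their levels were therefore not read here as the background of single genes. The subtraction of 5% free RNA did use their profile gene by gene, so for such genes it also took off these molecules. How far such molecules add to low counts in cells was not measured, and the highest folds depend on such low counts. On simulated counts of 18204 genes, 100% of 4-fold changes were recovered in each of the 3 comparisons, and 0 unchanged genes were counted. Intervals held the true fold in 96.5% of changed genes for effector and memory, 96.0% for activated and effector and 97.5% for activated and memory. These counts had Poisson noise alone around the averaged profile of the libraries compared. They check the code and say nothing of variation between libraries or cells, so nothing of false calls in the real data. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for scaling factors only.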

Results

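Single-cell RNA profiles were collected from mouse CD8 T cells in 3 conditions, with 1 library in each. The cells came from the spleens of male OT-I mice, a strain whose CD8 T cells nearly all carry one transgenic T cell receptor. All cultures were grown in a medium made to resemble blood. Activated cells were taken after 24 h on plate-bound anti-CD3 with anti-CD28 and IL-2. Effector cells were activated for 54 h and then kept for 144 h in IL-2, and memory cells had the same 54 h and then 144 h in IL-15. The authors kept 5859 activated, 8300 effector and 6666 memory cells. These held 59020793, 104040767 and 53844621 unique molecular identifiers (UMIs, each standing for 1 captured RNA molecule), with medians of 10012, 11129 and 7221.5 UMIs per cell. Ribosomal protein genes held 44.7% of the activated, 44.2% of the effector and 49.6% of the memory UMIs. There were no replicates, so no difference has a replicate check and none was tested. Levels are UMIs summed over the cells of a library and scaled by the library's total to the usual CPM unit, and ranges in parentheses after a fold are 95% intervals that cover counting error only.

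All 3 libraries carried the transcripts of CD8 T cells. Cd8a (chromosome 6, 71373427 to 71379173, plus strand, GRCm38), a chain of the CD8 co-receptor, stood at 222 CPM in activated, 167 in effector and 164 in memory cells. Cd3e, part of the T cell receptor complex, stood at 242, 289 and 307 CPM, and Il2rg, the receptor chain that IL-2 and IL-15 share, at 105, 114 and 141 CPM. The CD8 T cell marker list had a median log2 fold of -0.63 for activated over effector, -0.35 for activated over memory and -0.09 for effector over memory, the last of which was 0.02 in cells with no UMI of 4 cycle genes. Of the list of CD4 and regulatory T cell markers, 2 of 3 measured genes were at least 2-fold higher in effector than in memory cells, with a median of 1.36, and 3 of 3 were higher in effector than in activated cells, with a median of -2.57. The measured genes were Ctla4, Zbtb7b and Ikzf2, while Cd4 stood at 0.0339, 0.0288 and 0 CPM and Foxp3 at 0.136, 0.250 and 0.706 CPM in activated, effector and memory cells. The natural killer cell list had medians of -0.24 for effector over memory (1.03 with a minimum of 50 CPM), -1.65 for activated over effector and -1.94 for activated over memory. No measured member of the B cell, gamma-delta T cell or erythroid marker lists reached 10 CPM in the cells of any library. Only 1 of 6 gamma-delta T cell genes and 8 of 10 B cell genes were matched. The gamma-delta list therefore says little about such cells. Of the antigen-presenting cell list, 1 gene did: H2-Ab1, a class II major histocompatibility gene, stood at 0.610 CPM in activated, 90.4 in effector and 29.8 in memory cells. Its partner chain H2-Aa stood at 0.288, 1.01 and 0.650 CPM, and Cd74, the invariant chain of the same complex, at 6.69, 4.85 and 2.58 CPM. Fcer1g, a signalling chain common in myeloid and natural killer cells, was 9.51-fold (8.53 to 10.6) higher in effector than in memory cells. The myeloid list of 3 measured genes had a median of 0.77, or -0.07 with totals that leave out ribosomal protein and mitochondrial genes. Those totals raise every CPM, so the members at 10 CPM or more need not be the same 3. They moved the median of all genes by only -0.16.

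The comparison of effector with memory cells asks what 144 h in IL-2 or in IL-15 leaves behind after the same activation. The granzyme genes given here, which serve killing, were far apart. Gzma (chromosome 13, 113093825 to 113100981, minus strand), a granzyme, was 39.6-fold (38.6 to 40.6) higher in effector cells, at 4329 against 109 CPM. Gzmb (chromosome 14, 56258838 to 56262260, minus strand) was 6.03-fold (5.94 to 6.13) higher, at 1778 against 295 CPM. Gzmd (chromosome 14, 56129556 to 56132608, minus strand) was 408-fold (301 to 566) higher, Gzme was 226-fold (169 to 309) higher, and Gzmg had no UMI in memory cells, which puts it at least 1618-fold higher in effector cells against a floor of 3 counts. Memory cells held 3.69-fold (3.66 to 3.72) more Ccl5 (chromosome 11, 83525778 to 83530518, minus strand), a chemokine of memory and effector CD8 cells, at 3355 against 909 CPM.

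By the fixed rule of at least 2-fold and at least 10 CPM in the higher library, 291 genes were higher in effector and 90 in memory cells, among 6575 genes at 10 CPM or more in either. Of the genes that differed, 76.4% were higher in effector cells. With totals that leave out ribosomal protein and mitochondrial genes the split was 323 to 241, or 57.3%, and among cells with no UMI of 4 cycle genes it was 339 to 178, or 65.6%. That selection also changes the states compared, since 1706 of its 1769 memory cells were Tem and 63 were Tcm. Those totals moved the median of all genes by -0.16 on the log2 scale, and that selection of cells by -0.12.

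Among the receptor chains of the cytokines themselves, Il2ra passed the fixed rule, and Il2rb, Il2rg and Il15ra did not. Il2ra (chromosome 2, 11642807 to 11693193, plus strand), the high-affinity IL-2 receptor chain, was 8.92-fold (8.43 to 9.43) higher in effector cells, at 215 against 24.1 CPM. Il2rb, which serves both cytokines, was 1.77-fold (1.71 to 1.82) higher in effector cells, and Il15ra was 1.75-fold (1.54 to 1.98) higher in memory cells, at 8.88 against 5.07 CPM. Il7r, the IL-7 receptor chain usually tied to memory, was 3.64-fold (3.36 to 3.95) higher in effector cells. Of 19 measured cytokine receptor and STAT5 target genes, 4 were at least 2-fold higher in effector and 1 in memory cells, with a median log2 fold of 0.01 that changed sign under 4 settings, to -0.14 with totals that leave out ribosomal protein and mitochondrial genes. Lta, a tumour necrosis factor family cytokine, was 4.91-fold (4.44 to 5.44) higher in effector cells.

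The list of memory and naive T cell genes had a median of -0.81, with 4 of 18 measured members at least 2-fold higher in memory cells, 1 higher in effector cells and the others within 2-fold. These counts use the scale with a pseudocount of 1 CPM. A plain ratio just above 2, as for Eomes below, can fall short of 2-fold on it. Tcf7 (chromosome 11, 52252371 to 52283014, minus strand), a transcription factor that keeps T cells able to renew, was 3.51-fold (3.37 to 3.66) higher, at 119 against 33.9 CPM. S1pr1, which lets T cells leave lymph nodes, was 2.44-fold (2.29 to 2.61) higher, Cxcr3 2.62-fold (2.43 to 2.83) and Klf3 3.73-fold (3.26 to 4.28). Dapl1, at 171 CPM in memory cells, was 6.24-fold (5.99 to 6.51) higher there, and Eomes, a transcription factor of memory CD8 cells, was 2.02-fold (1.94 to 2.11) higher. The list of inhibitory receptor and exhaustion genes went the other way: 6 of 9 measured members were at least 2-fold higher in effector cells and 1 was lower, with a median of 1.32. Havcr2 (TIM-3) was 29.6-fold (24.4 to 36.3) higher in effector cells, Ctla4 4.27-fold (4.01 to 4.56), Lag3 3.28-fold (3.10 to 3.47) and Entpd1 (CD39) 3.42-fold (3.02 to 3.87). Of the cytotoxic list, 9 of 23 members were higher and 2 lower in effector cells, and its median of 0.10 became -0.05 with totals that leave out ribosomal protein and mitochondrial genes.

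Genes for glucose use and low oxygen were higher in effector cells. Of the glycolysis list, 10 of 19 measured members were at least 2-fold higher in effector and 0 in memory cells, with a median of 1.07, at percentile 100 of 10000 random lists matched on expression. Slc2a3 (chromosome 6, 122727809 to 122801640, minus strand), a glucose transporter, was 6.01-fold (5.65 to 6.40) higher, Pkm 2.86-fold (2.82 to 2.91) and Hk2, the first enzyme of glycolysis, 2.82-fold (2.70 to 2.94). Of the hypoxia list, 7 of 13 were at least 2-fold higher, with a median of 1.16. Ero1l, an oxidase of protein folding, was 4.36-fold (4.16 to 4.57) higher, and Bnip3, a mitophagy receptor, 3.74-fold (3.603 to 3.87). Metal-binding metallothioneins Mt2 and Mt1 were 10.4-fold (10.1 to 10.7) and 7.07-fold (6.97 to 7.17) higher in effector cells.

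Lipid and amino acid genes differed in part. Cholesterol synthesis had 9 of 20 measured members at least 2-fold higher in effector cells and a median of 0.95, with Hmgcs1 2.98-fold (2.79 to 3.18) and Fdps 2.88-fold (2.71 to 3.07) higher. Scd2, a fatty acid desaturase, was 3.39-fold (3.27 to 3.51) higher, and the fatty acid synthesis list had a median of 0.42. Asns (chromosome 6, 7675169 to 7693254, minus strand), which makes asparagine from aspartate and glutamine, was 7.74-fold (6.23 to 9.73) higher in effector cells, at 12.5 against 1.62 CPM. The memory level rests on 87 UMIs, and Asns stood at 3.73 CPM (1.71 to 7.08) in memory barcodes of 1 to 50 UMIs. How much of so low a level is background was not measured. Atf4, the transcription factor of the amino acid response, was 2.39-fold (2.31 to 2.48) higher and Trib3 3.31-fold (2.88 to 3.82), and the list of ATF4 and integrated stress response genes had a median of 0.64 with 4 of 14 members at least 2-fold higher. Cytosolic tRNA synthetases had a median of 0.55, with Cars 2.99-fold (2.61 to 3.44) and Iars 2.89-fold (2.61 to 3.20) among the 4 of 20 members that were at least 2-fold higher. Amino acid transporters had a median of 0.21, which was -0.17 with a minimum of 50 CPM and -0.20 in cells with no UMI of the 4 cycle genes.

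Genes of mitochondrial respiration differed little in size between effector and memory cells. The nuclear respiratory chain list had a median of 0.19, with 0 of 57 members at 2-fold. This small shift lay at percentile 98.1 of the random lists matched on expression. The mitochondrially encoded list had a median of 0.09, at percentile 63.6. The TCA cycle list had a median of 0.13 (-0.05 in cells with no UMI of the 4 cycle genes), and fatty acid oxidation one of 0.14 (-0.01 with totals that leave out ribosomal protein and mitochondrial genes). One-carbon genes had a median of 0.15, pentose phosphate genes 0.31 and ribosome biogenesis genes 0.17, which became -0.46 in cells with no UMI of the 4 cycle genes. Purine and pyrimidine genes had a median of 0.07 and polyamine genes 0.10, which were -0.11 and -0.10 in cells with no UMI of the 4 cycle genes. Other non-essential amino acid synthesis had one of 0.27, which was -0.20 in those same cells. The heat shock and immediate early list had a median of 0.47, and Jund in it was 3.54-fold (3.42 to 3.67) higher in effector cells. The p53 and apoptosis list had a median of -0.28, although Cdkn1a, the p21 cycle inhibitor, was 2.14-fold (2.09 to 2.20) higher in effector cells.

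**Figure D1:**
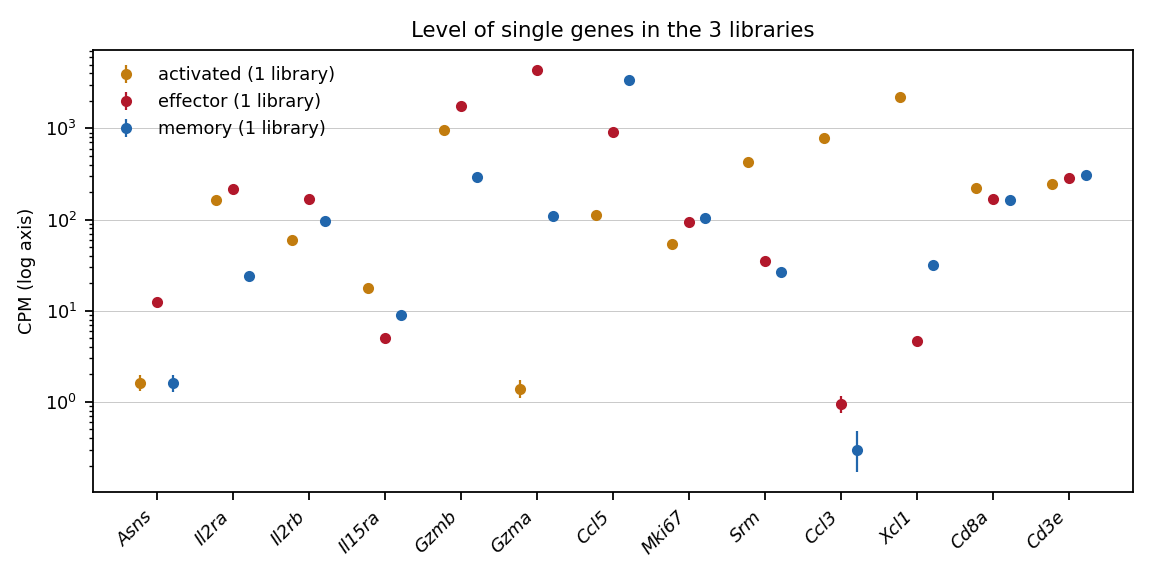
Levels of 13 genes in the 3 libraries, in CPM on a log axis; points are libraries and bars are 95% Poisson intervals of the count, mostly smaller than the points. Asns stood at 12.5 CPM in effector cells and at 1.63 and 1.62 CPM in activated and memory cells, while Cd8a lay between 164 and 222 CPM.

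The comparison of activated with effector cells sets 24 h of stimulation against the state reached 144 h after activation ended in IL-2. The chemokines Ccl3, Ccl4 and Xcl1 and the cytokine gene Ifng were far higher in activated cells, while the chemokine Ccl5 was lower there, at 112 against 909 CPM. Ccl3 (chromosome 11, 83647844 to 83649355, minus strand) was 840.4-fold (689 to 1035) higher in activated cells, at 792 against 0.942 CPM, and Xcl1 469.9-fold (429.8 to 515), at 2186 against 4.65 CPM. Ccl4 was 108-fold (103 to 113) higher, and Ifng, which encodes interferon gamma, 41.2-fold (37.3 to 45.6). The immediate early receptor Nr4a1 was 178-fold (124 to 264) higher. Effector cells were higher for the granzymes given here. Gzma stood at 1.39 CPM in activated cells, 3116-fold (2510.2 to 3918) below effector cells. That level rests on 82 UMIs, and the one of Ccl3 in effector cells on 98. How far molecules of other libraries add to such low counts was not measured, so these folds are uncertain beyond their intervals. Gzmd had no UMI in activated cells and was at least 6254-fold higher in effector cells. Gzmb differed less, at 963 against 1778 CPM.

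In this comparison 1405 genes were at least 2-fold higher in activated and 1136 in effector cells, of 7128, and the median of all genes was 0.22. With no minimum level the majority turned, with 1754 higher in activated and 2010 in effector cells. Early T cell activation genes were higher in activated cells for 14 of 20 measured members, with a median of 2.40. Genes that build ribosomes were higher for 22 of 24, with a median of 2.01, and Nop16 and Nolc1 were 10.8-fold (10.1 to 11.5) and 8.27-fold (7.90 to 8.66) higher. Srm (chromosome 4, 148591503 to 148594993, plus strand), which makes spermidine, was 12.2-fold (11.7 to 12.6) higher, and Odc1, the first enzyme of polyamine synthesis, 4.18-fold (4.10 to 4.27). Purine and pyrimidine synthesis genes were higher for 12 of 25 and lower for 1, with a median of 0.99. One-carbon genes were higher for 6 of 12, with a median of 0.70, at percentile 89.0 of random lists matched on expression. Shmt1 and Mthfd1 stood at 34.4 and 37.6 CPM against 6.73 and 8.35. Cycs, which encodes cytochrome c, was 4.73-fold (4.64 to 4.82) higher, and Aars, an alanyl-tRNA synthetase, 4.53-fold (4.37 to 4.68). Bcat1, a branched-chain amino acid transaminase, was 8.23-fold (7.52 to 9.01) higher, while Ass1, which serves arginine synthesis, was 6.85-fold (6.40 to 7.35) lower, and Asns was 7.69-fold (6.25 to 9.56) lower in activated cells. The Asns level in activated cells rests on 96 UMIs.

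Effector cells were higher for genes of glucose use, killing and movement. Glycolysis had 14 of 19 measured members at least 2-fold higher and 1 lower in effector cells, with a median of -1.71, and hypoxia had 11 of 13, with a median of -2.07. Bnip3 stood at 4.35 against 233 CPM and Aldoa, an enzyme of glycolysis, at 294 against 2160.0 CPM. Cytotoxic genes were higher in effector cells for 17 of 25 members and lower for 3, with a median of -2.49. Migration and adhesion genes were higher in effector cells for 9 of 16 and lower for 1, with a median of -1.21. The chemokine receptor Ccr2 stood at 0.136 against 329 CPM. Calcium-binding S100a4 and S100a6 and the interferon-induced Ifitm1 were 794-fold (645 to 990.4), 407-fold (371 to 448) and 7841-fold (5931 to 10599) higher in effector cells. Ifitm1 had only 49 UMIs in activated cells, so the same limit holds. The inhibitory receptor and exhaustion list had a median of -1.23, with Havcr2 88.8-fold (64.6 to 126) higher in effector cells and Cd200 116-fold (95.2 to 143) higher in activated cells. Cdkn1a was 26.4-fold (24.5 to 28.5) higher in effector cells, and Ddit4, a brake on mTOR signalling, 34.6-fold (30.4 to 39.6).

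The cholesterol synthesis median was -0.00 and the memory and naive median 0.05, and both changed sign under other settings, the first to 0.24 in cells with no UMI of the 4 cycle genes and the other to -0.19 without the Naive cells.

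The comparison of activated with memory cells asks the same of the IL-15 arm. Activated cells were again higher for Ccl3, Ccl4, Xcl1, Ifng and ribosome building, and memory cells for Ccl5, Ccr2 and Bcl2. Ccl3 was 2664-fold (1640.2 to 4661) higher in activated cells, Ccl4 137-fold (127 to 147), Xcl1 68.9-fold (65.7 to 72.3) and Ifng 48.6-fold (42.0 to 56.7). The Ccl3 fold rests on 16 UMIs in memory cells. Irf8, a transcription factor, was 11.9-fold (11.2 to 12.7) higher and Srm 16.3-fold (15.5 to 17.2). Memory cells were higher for Ccl5 by 30.0-fold (29.3 to 30.7), Bcl2, which protects from cell death, by 5.48-fold (5.34 to 5.61), and Ccr2 by 3012-fold (1528 to 6977). Il2ra was 6.75-fold (6.37 to 7.16) higher in activated than in memory cells.

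In this comparison 1456 genes were at least 2-fold higher in activated and 954 in memory cells, of 7022, a share of 60.4% for activated cells. With totals that leave out ribosomal protein and mitochondrial genes the split was 1386 to 1502, or 48.0%. The median of all genes was 0.25 and moved by -0.20 with those totals and by -0.11 with TMM factors. Early T cell activation genes were higher in activated cells for 15 of 20 members, with a median of 2.82, and ribosome biogenesis genes for 22 of 24, with a median of 2.19. Cytosolic tRNA synthetases were higher for 14 of 20, with a median of 1.25, and polyamine genes for 5 of 8, with a median of 1.47. Purine and pyrimidine genes were higher for 13 of 25 and lower for 1, and one-carbon genes were higher for 6 of 12, with medians of 1.12 and 1.04. Cholesterol synthesis genes were higher for 9 of 18, with a median of 0.98, and amino acid transporters for 5 of 8, with a median of 1.21. Slc7a5, a transporter of large neutral amino acids, was 4.95-fold (4.501 to 5.45) higher in activated cells. Asns stood at 1.63 against 1.62 CPM, a fold of 1.01 (0.745 to 1.36) that spans no difference.

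Memory cells were higher for cytotoxic genes in 11 of 19 members and lower in 4, among them Gzmb at 963 against 295 CPM, with a median of -2.30, and for hypoxia genes in 7 of 13, with a median of -1.10. Glycolysis was higher in memory cells for 6 of 18 members and lower for 1, with a median of -0.43. Migration and adhesion genes had a median of -1.56 and p53 and apoptosis genes -1.35. Klrb1c, a natural killer receptor, was 185-fold (101 to 387) higher in memory cells and Gzmm, a further granzyme, 186-fold (117 to 314). The interferon response median was -0.67, but it was 0.24 by the mean of each cell's own CPM, 0.20 with a minimum of 50 CPM and 0.03 in thinned cells. The memory and naive median was -0.36 and became 0.10 by the mean of each cell's own CPM.

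**Figure D2:**
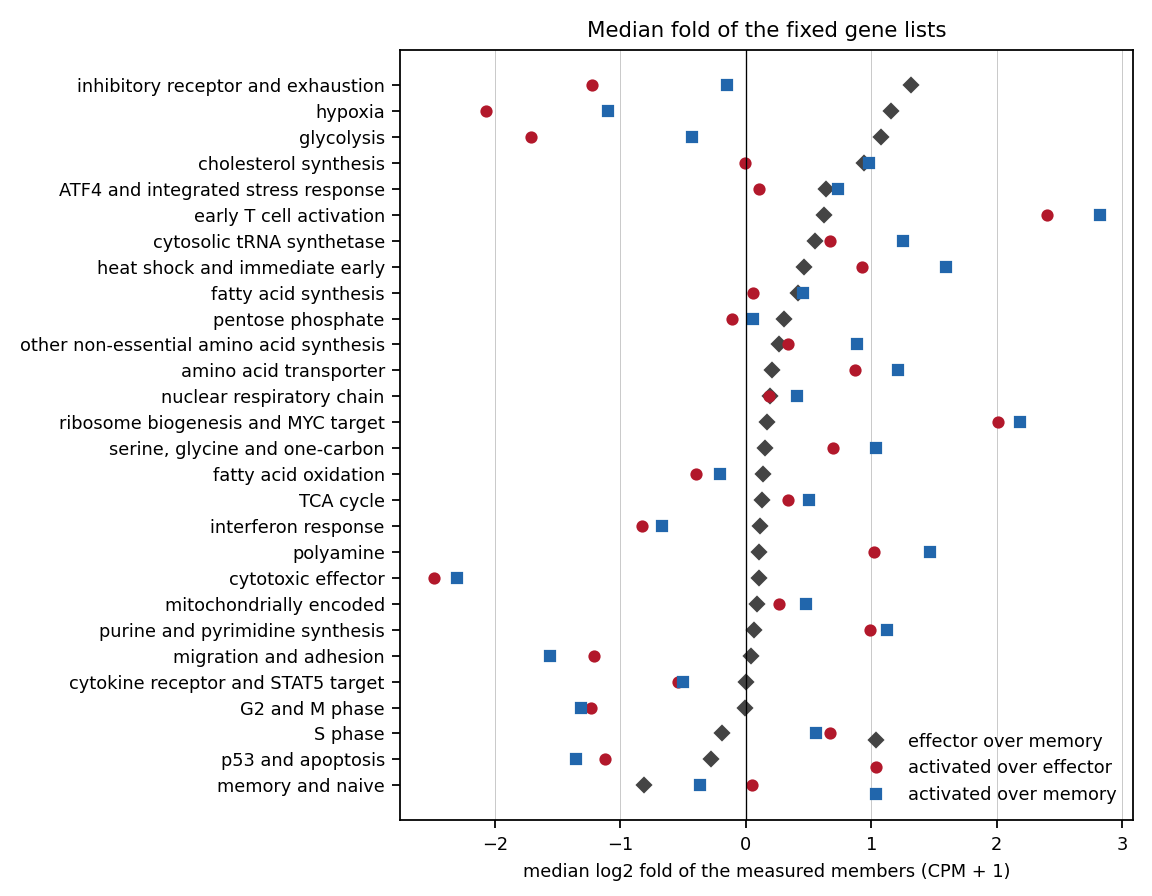
Median log2 fold of the measured members of 28 gene lists, for effector over memory (diamonds), activated over effector (circles) and activated over memory (squares); the vertical line marks 0. The early T cell activation list lay at 2.40 and 2.82 in the comparisons with activated cells, and the glycolysis list at 1.07 for effector over memory and -1.71 for activated over effector.

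Genes of the late cell cycle were lower in activated cells than in either later library. The G2 and M phase list had a median of -1.23 for activated over effector, with 32 of 52 members at least 2-fold higher in effector cells, and of -1.31 for activated over memory, with 33 of 52. S phase genes had medians of 0.67 and 0.56, above the median of all genes, and Ung, a DNA repair glycosylase, was 22.03-fold (20.03 to 24.3) higher in activated than in effector cells. Ccnb2, a mitotic cyclin, stood at 5.30, 119.8 and 112 CPM. Between effector and memory cells the G2 and M phase median was -0.00 and changed sign to 0.20 in cells with no UMI of the 4 cycle genes and to 0.15 by the mean of each cell's own CPM. The S phase median for effector over memory was -0.19, at percentile 0.03 of random lists matched on expression. Of its 39 measured members, 0 differed by 2-fold. After each cell was thinned to 1600 UMIs, an Mki67 UMI was found in 5.31% of activated cells (95% exact binomial interval 4.73 to 5.94), 12.1% of effector cells (11.4 to 12.9) and 12.5% of memory cells (11.7 to 13.3). Without thinning the shares were 28.2%, 52.8% and 43.5%, at medians of 10012, 11129 and 7221.5 UMIs. Cells named Naive, in which Mki67 would not be active, had it in 0.511% (0.106 to 1.49) after thinning, with 404 of the 991 left out for low depth.

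The authors named 11 states by the average level of markers in fine clusters of the same cells. The markers are not given in the sources used here, so levels of T cell state genes are not independent of those names. Activated cells fell into Naive, Early, Mid, Mid-Late and Late states, effector cells into Undiff, Tcmp, Temp and Teff, and memory cells into Tcm and Tem. Late cells made up 20.4% (19.3 to 21.4) of activated cells, Teff cells 33.7% (32.6 to 34.7) of effector cells and Tcm cells 62.3% (61.1 to 63.5) of memory cells. Each state lies in 1 library.

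Across the activated states, Srm was already higher in Early than in Naive cells, and Ccl3 and Ifng were highest in Late cells. Srm stood at 41.3 CPM in Naive, 207 in Early, 389.7 in Mid and 523 in Late cells. Ccl3 stood at 33.7 CPM in Mid, 339.8 in Mid-Late and 2836 in Late cells, and Ifng at 14.1, 51.1 and 596 CPM. Summed interferon response genes went the other way, at 3849 CPM in Naive, 2005 in Early and 579 in Late cells. One-carbon genes summed to 221 CPM in Naive and 999 in Late cells. Late over Naive, the ribosome biogenesis median was 2.43, with 23 of 24 members at least 2-fold higher, and fatty acid oxidation was -0.43. Over all 6896 measured genes that median was 0.62, with 2582 at least 2-fold higher and 980 lower in Late cells. The depth of Naive cells, at a median of 1645.0 UMIs against 10765.0 in Late cells, limits what single genes show there.

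Within effector cells, Tcmp and Temp held the higher glycolysis sums and Teff more of the ribosome biogenesis genes than Tcmp. Glycolysis genes summed to 13772 CPM in Tcmp and 14173 in Temp, 10263 in Undiff and 8755 in Teff cells, against 4911 in Tcm and 4891 in Tem cells of the memory library. The sums rest on abundant members: Teff over Tcmp, the glycolysis median was -0.14, with 1 of 19 members at least 2-fold higher in Teff and 0 in Tcmp. Aldoa stood at 3249 CPM in Temp and 1594 in Teff cells, while Hk2 stood at 92.0 and 151 CPM. Over Tcmp, Teff cells were at least 2-fold higher for 16 of 22 ribosome biogenesis genes, with a median of 1.54, and the tRNA synthetase median was 0.69. Asns was at 17.9 CPM in Teff and 12.7 in Undiff cells and at 5.50 and 4.79 in Tcmp and Temp cells. Amino acid transporter Slc7a5 stood at 30.9 CPM in Teff and 3.05 in Temp cells.

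Within memory cells, Tcm cells held the cycle genes. Over Tcm, Tem cells were at least 2-fold lower for 51 of 52 G2 and M phase genes and 39 of 41 S phase genes, with medians of -3.02 and -2.20. The one-carbon median was -1.12 and the cholesterol median -0.92. Glycolysis was at -0.12, and 0.06 with totals that leave out ribosomal protein and mitochondrial genes. Over all 6509 measured genes the Tem over Tcm median was -0.15, with 77 at least 2-fold higher and 677 lower in Tem cells. Tem cells had a median of 4505.0 UMIs per cell against 9130.0 in Tcm cells. Ccl5 stood at 6430.2 CPM in Tem and 2459 in Tcm cells, and Gzmb at 153 and 336 CPM, a log2 fold of -1.13 that was 0.15 in cells with no UMI of the 4 cycle genes, which were 1706 Tem and 63 of 4153 Tcm cells.

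**Figure D3:**
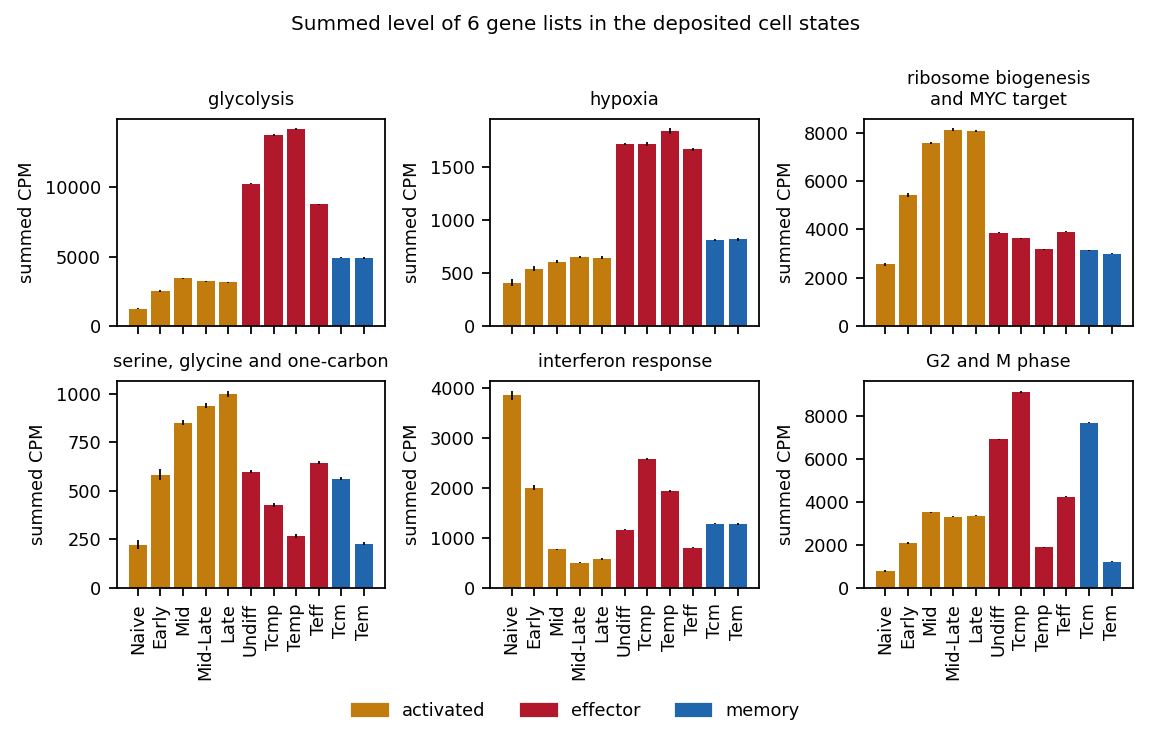
Summed CPM of 6 gene lists in the 11 deposited cell states, on axes from 0; bars are states, coloured by library, and error bars are 95% Poisson intervals. Glycolysis genes summed to 8755 CPM in Teff, the lowest effector state, and to 4911 CPM in Tcm cells, and interferon response genes to 3849 CPM in Naive cells.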

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

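The haemoglobin test and the state-mix test below were chosen only after the result was seen, the other tests were written after the patterns were seen but before they were run, and the rod genes were picked from the small barcodes. In barcodes of 1 to 50 UMIs, which the authors did not keep as cells, 12 rod photoreceptor genes summed to 2172.0 CPM in the activated, 2066 in the effector and 3527 in the memory library, and 4 haemoglobin genes to 302.2, 295.2 and 541.8 CPM. As counts these were 8453, 9101 and 8507 rod UMIs and 1176, 1300 and 1307 haemoglobin UMIs. The small barcodes held 3891801, 4404515 and 2412244 UMIs in all, so the higher CPM in the memory library goes with its smaller total. In the kept cells 1 of the 12 rod genes, Sag, passed 1 CPM, at 4.74 CPM in activated cells. Gzma stood at 175.2 CPM in the small barcodes of the activated library against 1.39 CPM in its cells, and Ccl3 at 20.4 CPM in those of the effector library against 0.942 CPM in its cells. These signals stand in barcodes outside the comparisons of the report, except that the subtraction of 5% free RNA used the profile of these barcodes.

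The pattern is transcripts foreign to a library in its small barcodes. Of the UMIs of Gzma, Ifitm1, S100a6, Gzmd and S100a4 in the small barcodes of the activated library, 86.9% lay on barcodes that are cells in another library, 41.9 times the share of Xcl1, Ccl3 and Ccl4 UMIs, which argues against free RNA of the library's own suspension and is consistent with molecules carried over between the libraries. For a source outside the series, 65 of 116 activated barcodes with at least 3 haemoglobin UMIs had them in another library as well, against 0.0351 by chance. Carry-over may therefore also account for haemoglobin. Barcodes of a library of the series that were not kept as cells could give the same sharing. The test thus cannot tell a source outside the series from one within it. For rod genes the ratio to chance was 803, but it rests on 1 shared barcode of 18, so a source outside the series and another origin cannot be told apart. No biological explanation was tested.

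Glycolysis and hypoxia genes were higher in effector than in memory cells, with medians of 1.07 and 1.16. Among cells with no UMI of 4 cycle genes the medians were 1.23 for glycolysis and 1.12 for hypoxia, so both differences remained there. That selection held 1706 Tem among 1769 memory cells, and 1186 of 8300 effector cells with 2 of 1572 Tcmp cells. A cell of low depth also passes it more easily. It therefore changes states and depth and does not isolate the share of cycling cells. The lower of the glycolysis medians with TMM and size factors was 1.05, but these tests moved the median of all genes by at most -0.03. Totals without ribosomal protein and mitochondrial genes moved the median of all genes by -0.16. They gave 0.94 for glycolysis and 0.92 for hypoxia, so scaling could account for a part. For a different mix of states, Teff was the lowest effector state and Tcm the highest memory state. The summed glycolysis level of Teff was 1.78 times that of Tcm, so no other shares of these states would level the sums. But no state occurs in both libraries, so the test cannot tell state from library. It was run for glycolysis alone, and the sums rest on abundant members. The difference between IL-2 and IL-15 may account for the higher glycolysis and hypoxia genes, as a hypothesis found on the same data and untested. The lower viability of the memory culture stays open.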

How the results depend on the processing

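The state comparisons, all deposited cells and leaving out Naive cells were settings chosen only after the data were seen, as was the rule that a state needs 50 cells under a setting, which leaves no value for Teff over Tcmp among cells with no UMI of 4 cycle genes. Counts of genes and Mki67 shares stayed within 1.5 times the main count or within the interval in 82 of 102 results and settings. With totals without ribosomal protein and mitochondrial genes, 241 genes were higher in memory than in effector and 1502 higher in memory than in activated cells; those totals raise every CPM and move the median of all genes towards memory cells. A pseudocount of 5 CPM left 53 genes higher in memory than in effector cells. With no minimum, 571 genes were higher in effector than memory, 154 in memory than effector, 2010 in effector than activated (against 1754 the other way, so the majority turned) and 1637 in memory than activated cells; with a minimum of 50 CPM there were 106 and 30 between effector and memory, 653 and 389 between activated and effector, and 720 and 308 between activated and memory, since the minimum sets how many genes are counted. Among cells with no UMI of 4 cycle genes, 178 genes were higher in memory than in effector cells, and the cause was not tested. Mki67 shares were 28.2%, 52.8% and 43.5% for activated, effector and memory cells without thinning and 2.80%, 6.61% and 6.83% when thinned to 800 UMIs, since fewer UMIs per cell find fewer transcripts. The median of the antigen-presenting list for effector over memory was -0.0265 with no minimum (main 1.57, 1 member), because genes near 0 CPM then enter. Gzmb for Tem over Tcm was 0.15 among cells with no UMI of 4 cycle genes (main -1.13), which rests on 63 Tcm cells, and the cause was not tested. Of 202 list medians, 43 changed sign under some setting, 1 of them with a main size of at least 1, and of 489 named gene values 23 did, 1 of them with a main size of at least 1. The median of all genes moved by -0.23 and -0.25 with no minimum and by 0.14 and 0.20 with a minimum of 50 CPM, for activated over effector and over memory. Depth limits genes below about 1 CPM, and no replicate could be left out. No paired analysis was possible because each group has 1 library. Removal of called doublets gave no value, since 0 cells were called.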

Other observations

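No test in this part was chosen after a result was seen, since none is offered. The 44 effector cells that the authors left out as apoptotic held 200310 UMIs, of which 0.0639% (0.0533 to 0.0760) came from mitochondrially encoded genes. Prdx1, a peroxide-removing enzyme, stood at 1473 CPM in them against 243.0 in the kept effector cells, and proteasome genes Psmb2 and Psmb5 at 519 and 199.7 CPM against 113.2 and 45.5. Cdc20 and Cdk1, which drive mitosis, stood at 194.7 and 264.6 CPM against 38.9 and 55.4. Cd8a stood at 49.9 CPM against 167.2, Cd3e at 69.9 against 288.8 and Gzmb at 504.2 against 1778. The Prdx1, Psmb and cycle genes were chosen after their values were seen.

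Small barcodes of the effector and memory libraries held Xcl1, Ccl3 and Ccl4. Of these UMIs, 84.1% (81.3 to 86.6) in the effector library and 77.7% (74.8 to 80.4) in the memory library lay on barcodes that are cells in another library. Of the Gzma, Ifitm1, S100a6, Gzmd and S100a4 UMIs in the small barcodes of the memory library, 25.5% (24.7 to 26.4) did.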
